A study of Drosophila melanogaster with 12 samples.

How the data were processed

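Transcripts of whole male Canton-S larvae were measured on 12 Affymetrix arrays, 3 biological replicates for each of 4 groups (feeding mid-L3 or wandering larvae, control or high sugar food). Per the labels, biotin-labelled cRNA was made from 2 ug of total RNA per sample. The values deposited by the authors are 1 intensity per probe set and array on a linear scale. The software that summarized probes into probe sets, its normalization and its filters are not given in the sources used here. The values were never negative, 41 to 57 values per array lay at exactly 1, the highest value was 15822, and the median per array was 62.2 to 82.4. No detection calls or probe sequences were analysed here, so the number of arrays is the stated limit on precision.

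Of 18952 probe sets, 183 were array controls and were left out. The platform's gene table listed 14049 probe sets, of which 13647 had 1 gene symbol and 402 had several, and 4720 probe sets that were not controls were unlisted and stayed unnamed. Symbols were updated through the Entrez identifier for 13544 of the 13647, and 103 kept the name of the table. Probe sets with several genes were not named. For the 1094 genes with several probe sets, the one with the highest mean was used, which left 11982 genes, and genes under the 30th percentile of the mean were left out, which left 8387 genes to test. Values were transformed as log2 of intensity plus 12.7, the 20th percentile of all values, and then quantile normalized. The rule for normalizing was written before the data were examined: arrays were to be quantile normalized unless their trimmed means (2% trimmed at each end) lay within 1% or their medians within 0.05 on the log2 scale, and neither held.

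A linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (residual df 8, prior df 4.41, eBayes with an intensity trend). The comparisons were high sugar against control food in wandering larvae and in mid-L3 larvae, the difference of these diet effects (the interaction), and wandering against mid-L3 larvae on each food. P values were adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. All adjusted p values of genes in the text come from limma's moderated t test. Gene lists written from general knowledge, 24 of pathways and 11 of tissue and sex markers, were tested with camera at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Of these 35 lists, 32 had at least 5 tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

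The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 8 largest increases and 8 largest decreases among genes that passed and whose groups did not overlap, up to 3 members per list with the smallest adjusted p, and for both diets together the 6 genes per direction with the largest smaller change. It also took 22 genes of sugar and fat metabolism and of larval development whatever their change, of which 18 were tested. Thor, Uro, Ilp6 and Amy-p were not analysed here, since they had no tested probe set with 1 gene. The text names part of the genes the rule took.

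The wandering diet comparison was tested on simulated data, in which 200 of 8387 genes were changed singly and the 12 genes of 1 list were raised by a log2 change of 0.5. At a log2 change of 1, 92 of 100 genes were found (92%), with a median fitted change of 1.00, and at 0.5, 41 of 100 (41%). None of them had the wrong direction. Of the list, 7 genes were found. Of 152 genes called, 12 were unchanged (7.89%), and the mid-L3 comparison called 0 genes. The shifted list of 12 genes was the 1 list that passed camera, with adjusted p = 8.1e-18. Noise was drawn independently for each gene and with the same spread in all groups. The simulation therefore does not show how the calls of genes or lists behave with correlated genes or unequal spreads.

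The alternatives were the values as deposited, arrays centered on their medians, an added constant of 1 or 5 times larger, no filter or a filter at the 50th percentile, the mean of a gene's probe sets, all probe sets singly, the 6 compared arrays alone, the replicate number as a block, array weights, no intensity trend, a robust variance prior, a 2-fold change as a further condition, and each array left out in turn. Leaving out both control arrays numbered 1, a covariate for each array's position between the stages, the 6 control arrays alone with the number as a block, and a block in the control arrays alone among all 12 were added after the data were seen.

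Whether replicate numbers pair the arrays was checked on the deviations from the group means, since the labels do not say that a number marks a shared batch. Same-numbered control arrays of the stages correlated at 0.122 to 0.178 in all 3 pairs, and the other pairs of control arrays at -0.181 to 0.073. The same numbers gave the highest sum of the 6 ways to match these arrays. Chance gives this rank in 1 of 6 cases for each pair of groups, and all pairs of groups were checked, so a shared batch is not shown. Wandering control array 3 and wandering high sugar array 2, of unlike number, correlated at 0.389, so the numbers do not describe all structure shared between arrays. By the rule that every pair lie over 0.1, the numbers were taken to pair the arrays of the stage comparison on control food and of no other comparison of 2 groups. These control arrays also enter the difference between the diet effects of the stages.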

Results

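Transcript abundance was measured in whole male Drosophila melanogaster larvae of the wild-type strain Canton-S on 12 Affymetrix arrays. Control food held 0.15 M sucrose and high sugar food held 1 M sucrose. Wandering larvae of the last instar, which had left the food, had eaten their diet since hatching. Feeding larvae in the middle of that instar (mid-L3) had grown up on control food and spent their last 12 h on fresh control or high sugar food. Each of the 4 groups held 3 biological replicates, so the number of arrays limits the precision of every value below. The median intensity per array was 62.2 to 63.6 in mid-L3 larvae on control food, 64.6 to 65.0 in mid-L3 larvae on high sugar food, 79.1 to 80.4 in wandering larvae on control food and 80.1 to 82.4 in wandering larvae on high sugar food. Across probe sets, arrays of the same group correlated with Spearman's rho of 0.966 to 0.980, arrays of different diets within a stage with 0.962 to 0.974 and arrays of different stages with 0.830 to 0.876. The first principal component, which separated the stages, held 89.2% of the variance, and the second, which separated the diets within each stage, held 4.29%. Changes are given as log2 fold changes of intensity plus a constant of 12.7, which understates the change of dim genes, and 8387 genes were tested.

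The first comparison asked how growing up on high sugar food changed transcripts in wandering larvae. The cytochrome P450 gene Cyp4e3 was the most strongly raised, from an intensity of 44.0 ± 7.51 on control food to 4375 ± 1495 on high sugar food (SD, n = 3), a log2 change of 6.42 (SE 0.22, adjusted p = 6.1e-09). The largest decreases were those of the predicted lipase CG6271, with a log2 change of -6.95 (SE 0.36, adjusted p = 9.8e-08) and of the lipase Lip3, with -5.81 (SE 0.31, adjusted p = 1.1e-07), from 2592 ± 526 to 38.1 ± 12.8 (SD, n = 3). The transcript of the amylase-related protein Amyrel fell by 4.20 (adjusted p = 6.1e-09), that of the predicted peptidase CG12951 by 5.29 (adjusted p = 4.0e-08) and that of Jig by 3.97 (adjusted p = 1.7e-05). Malic enzyme (Men) rose by 1.59 and phosphoenolpyruvate carboxykinase (Pepck1) by 1.31. Other genes with large increases were CG3348 (4.46), CG13947 (3.58), ng2 (2.94), a gene named for the glue that larvae secrete from their salivary glands, and vanin-like (2.83), with adjusted p values of 4.9e-06, 2.2e-06, 1.9e-05 and 0.0012. For each of these genes but Men and Pepck1, which were named as members of gene lists, the rule for naming required the 3 arrays of one diet to lie apart from the 3 of the other, which chance alone gives for 10% of genes.

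Of the 12 lipogenesis genes tested, 6 rose in wandering larvae and none fell, and the count adjusted over the list alone was also 6. The list passed the camera test as higher (adjusted p = 2.8e-05, but adjusted p = 0.51 with an estimated correlation). Men (adjusted p = 4.5e-05), a source of NADPH, went from 745 ± 177 to 2018 ± 457 (SD, n = 3). The sugar-induced zinc finger gene sugarbabe (sug) rose by 2.20 (SE 0.24, adjusted p = 1.1e-04) and the fatty acid desaturase gene Desat1 by 1.11 (SE 0.14, adjusted p = 4.4e-04). Fatty acid synthase (FASN1) rose by 1.24 (SE 0.28, adjusted p = 0.0214). Its call ended without wandering control array 3 (adjusted p = 0.0878), high sugar array 1 (0.0821) or high sugar array 3 (0.0891), in a range of 9.9e-05 to 0.118 over all alternatives. Acetyl-CoA carboxylase (ACC) gave 0.20 with adjusted p = 0.38. Of the 11 genes for triglyceride storage, 3 rose and none fell, with 3 higher and 1 lower adjusted over the list alone and no call for the list (adjusted p = 0.12). They included the perilipin gene Lsd-1 (0.70, adjusted p = 4.9e-05), whose product sits on lipid droplets, and Seipin (0.76, adjusted p = 0.0014).

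The list of lipolysis and fatty acid oxidation genes held 5 higher and 1 lower of 14, or 7 higher and 1 lower adjusted over the list alone, and was called higher (adjusted p = 0.0060, but adjusted p = 0.51 with an estimated correlation). Its median was 0.30, whereas its mean was -0.12 because of Lip3, the member that fell. The thiolase gene yip2 rose by 0.72 (adjusted p = 6.9e-04) and the acyl-CoA oxidase gene Acox57D-d by 0.79 (adjusted p = 0.0031). The triglyceride lipase gene brummer (bmm) gave 0.59 with adjusted p = 0.065. It passed without wandering control array 2 (adjusted p = 0.0386) or high sugar array 2 (0.0312), within a range of 0.0108 to 0.245 over all alternatives. Of 27 genes of oxidative phosphorylation, 5 rose and none fell, or 7 and 0 adjusted over the list alone, with a median of 0.13 (adjusted p = 2.8e-05, but adjusted p = 0.51 with an estimated correlation). Cyt-c1, a subunit of respiratory complex III, rose by 0.41 (SE 0.06, adjusted p = 0.0016), a call that ended when the 6 wandering arrays were fitted alone (adjusted p = 0.0848, range 4.5e-05 to 0.0848).

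Among 18 genes of gluconeogenesis, trehalose and glycogen, 6 rose and 1 fell, or 6 and 2 adjusted over the list alone, and the list was called higher (adjusted p = 0.0057, but adjusted p = 0.51 with an estimated correlation). Pepck1 went from 2839 ± 107 to 6980 ± 467 (SD, n = 3, adjusted p = 1.1e-05). Trehalose-6-phosphate synthase (Tps1) rose by 1.17 (adjusted p = 5.2e-05), the trehalose transporter gene Tret1-1 by 0.44 (adjusted p = 0.0020) and fructose-1,6-bisphosphatase (fbp) by 0.78 (adjusted p = 0.0031). The fbp call ended with the wandering arrays fitted alone (adjusted p = 0.0571, range 1.9e-05 to 0.0571). The sorbitol dehydrogenase gene Sodh1 fell by 1.31 (adjusted p = 0.0026), and trehalase (Treh) gave -0.31 (adjusted p = 0.090). The glycolysis list had 1 higher of 12, glycerol-3-phosphate dehydrogenase (Gpdh1, 1.81, adjusted p = 8.7e-04), with adjusted p = 0.12 for the list. The list passed without wandering control array 1 (adjusted p = 2.5e-06) and with the stage position as a covariate (0.0253), in a range of 2.5e-06 to 0.44. The hexokinase gene Hex-C gave 0.60 (adjusted p = 0.0999). It passed with a smaller added constant of 1 (adjusted p = 0.0379, range 0.0379 to 0.358).

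Digestive enzymes moved in opposite directions in wandering larvae. Of 24 gut peptidase genes, 5 rose and 7 fell, or 6 and 11 adjusted over the list alone. The genes that fell belonged to the Jonah group of serine peptidases and included Jon99Ci with a log2 change of -3.62 (SE 0.18, adjusted p = 7.1e-08), Jon44E with -2.41 (SE 0.20, adjusted p = 1.3e-05) and Jon66Ci with -0.70 (SE 0.06, adjusted p = 1.4e-05). The list was called lower (adjusted p = 0.030, but adjusted p = 0.57 with an estimated correlation). The call ended without wandering control array 1 (adjusted p = 0.0539), control array 2 (0.116), high sugar array 2 (0.184) or high sugar array 3 (0.0578), within 8.8e-04 to 0.184 over the alternatives. Of 11 carbohydrase genes, 2 rose and 4 fell, Amyrel from 1845 ± 450 to 102 ± 17.9 (SD, n = 3) and the alpha-glucosidase gene tobi by 1.72 (adjusted p = 0.0053), whereas the maltase gene Mal-A7 rose by 1.26 (adjusted p = 0.0019). The carbohydrase list had adjusted p = 0.15, and 0.0021 without wandering control array 3, in a range of 0.0021 to 0.61. The list of midgut markers, which shares members with the peptidase list, had 2 higher and 3 lower of 11 (adjusted p = 0.13, and 0.0322 without wandering control array 3, range 0.0322 to 0.41).

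Detoxification genes held 4 higher and none lower of 27, or 8 and 0 adjusted over the list alone (adjusted p = 1.6e-04, but adjusted p = 0.51 with an estimated correlation). They included the cytochrome P450 gene Cyp4d1 (1.81, adjusted p = 1.4e-05) and the glutathione transferase genes GstE9 (1.71, adjusted p = 8.8e-05) and GstE7 (1.60, adjusted p = 0.0030). Of 8 immune effector genes, 2 fell and none rose (adjusted p = 0.12 for the list, and 0.0454 without a filter on dim genes). PGRP-SC2, which encodes an enzyme that degrades bacterial peptidoglycan, fell by 3.55 (SE 0.16, adjusted p = 3.8e-08), and PGRP-SB2, named for the size of its change, fell by 3.87 (SE 0.35, adjusted p = 2.2e-05). Autophagy and cell death genes held none called of 16 by limma, 7 with an unadjusted p under 0.05, and 1 higher and 4 lower adjusted over the list alone. That list was called lower (adjusted p = 0.038, but adjusted p = 0.51 with an estimated correlation). This call ended without wandering control array 2 (adjusted p = 0.116), high sugar array 1 (0.0775) or high sugar array 3 (0.114), in a range of 0.0178 to 0.116.

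Testis markers were called higher as a list in wandering larvae (adjusted p = 0.0055, but adjusted p = 0.51 with an estimated correlation) with a median of 0.24. None of the 12 passed in limma on its own, 4 had an unadjusted p under 0.05, and the list's call ended without wandering control array 1 (adjusted p = 0.0546, range 6.2e-04 to 0.0583). In the list for insulin, FOXO and TOR, 1 of 15 rose and 1 fell (adjusted p = 0.30 for the list). The adipokinetic hormone receptor gene AkhR rose by 1.36 (SE 0.14, adjusted p = 5.1e-05), while a dimmer probe set of the same gene gave -0.03. The insulin receptor (InR) gave -0.08 (adjusted p = 0.69), the insulin-binding protein gene ImpL2 gave 0.01 (adjusted p = 0.98) and the lipocalin gene NLaz gave -0.11 (adjusted p = 0.82). Of 17 genes of amino acid breakdown, 2 fell, Sardh by 0.81 (adjusted p = 0.010) and Hpd by 0.82 (adjusted p = 0.012). Both calls ended without both control arrays numbered 1 (adjusted p = 0.0573 and 0.0678, ranges 0.0018 to 0.0573 and 0.0037 to 0.0678). The storage protein gene Lsp2 gave 0.01 (adjusted p = 0.97) and the glue protein gene Sgs3 gave -0.01 (adjusted p = 0.997).

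In limma's test, 534 of the 8387 genes (6.37%) passed in wandering larvae, 299 higher and 235 lower, of which 144 changed at least 2-fold, 75 higher and 69 lower. Of the 32 gene lists tested, 8 passed camera, 6 higher and 2 lower, and none passed with an estimated correlation, where 1 had an unadjusted p under 0.05. The fry test called 9 lists as moving in a direction and 21 as changing either way. The count of genes was 275 without wandering control array 3, 317, 1421 and 295 without high sugar arrays 1, 2 and 3, and 328 without both control arrays numbered 1, where antimicrobial transcripts were raised. It was 213 with the 6 wandering arrays fitted alone and 2381 with estimated array weights. The median SD of a gene on the log2 scale was 0.130 on control and 0.169 on high sugar food in wandering larvae. In mid-L3 larvae it was 0.110 and 0.101. The main fit shares the spread over all groups, which tends to make p values too small in wandering and too large in mid-L3 larvae. The counts of the diet comparisons are therefore not on equal terms.

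**Figure D1:**
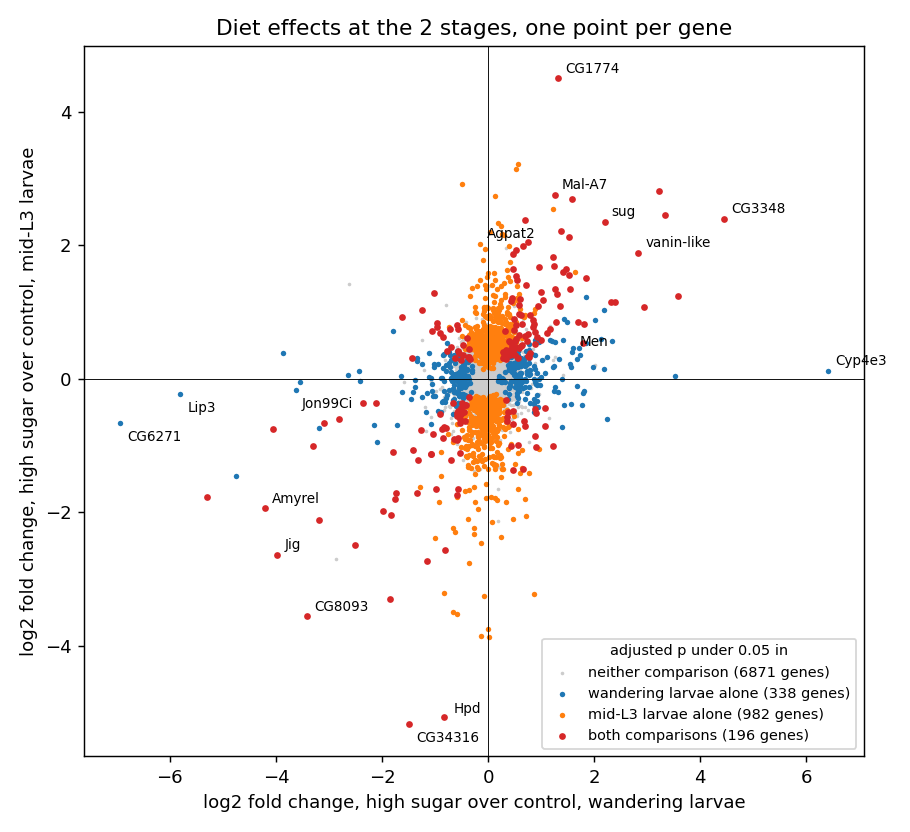
Each point is a gene, with its log2 fold change on high sugar food over control food in wandering larvae on the horizontal axis and in mid-L3 larvae on the vertical axis, colored by where it passed an adjusted p of 0.05. Cyp4e3 lies far to the right with a mid-L3 value of 0.12, Hpd far down with a wandering value of -0.82, and 196 genes passed at both stages.

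The second comparison asked what the last 12 h on high sugar food changed in feeding mid-L3 larvae. CG1774 rose most, from an intensity of 192 ± 44.8 to 5576 ± 143 (SD, n = 3), a log2 change of 4.50 (SE 0.32, adjusted p = 1.8e-06), and CG4716 rose by 3.22 (SE 0.37, adjusted p = 8.9e-05). The maltase gene Mal-A7 rose by 2.76 (SE 0.19, adjusted p = 1.8e-06), from 90.2 ± 8.14 to 724 ± 50.6 (SD, n = 3). CG34316 fell by 5.17 (SE 0.25, adjusted p = 8.2e-08). Hpd, whose product breaks down tyrosine, fell by 5.07 (SE 0.17, adjusted p = 2.5e-09), from 1846 ± 141 to 40.5 ± 12.3 (SD, n = 3), and CG13230 by 3.86 (SE 0.19, adjusted p = 8.4e-08).

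Of the 12 lipogenesis genes, 5 rose and none fell in mid-L3 larvae, or 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.0081, but adjusted p = 0.54 with an estimated correlation). sug rose by 2.35 (SE 0.24, adjusted p = 3.5e-05), from 376 ± 33.6 to 2226 ± 171 (SD, n = 3), ACC by 1.07 (SE 0.13, adjusted p = 1.0e-04) and Desat1 by 0.69 (SE 0.14, adjusted p = 0.0062). FASN1 gave 0.18 (adjusted p = 0.73), at intensities of 12509.9 and 13866 near the top of the scale, where the highest value was 15822. It passed with the 6 mid-L3 arrays fitted alone (adjusted p = 0.0047, range 0.0047 to 0.83). Of 11 genes for triglyceride storage, 5 rose and 1 fell, or 5 and 2 adjusted over the list alone. The acyltransferase gene Agpat2 rose by 2.03 (SE 0.10, adjusted p = 1.4e-07), Lsd-1 by 0.65 (SE 0.07, adjusted p = 5.2e-05) and Seipin by 0.67 (SE 0.11, adjusted p = 0.0016). That list was called higher (adjusted p = 0.044, but adjusted p = 0.52 with an estimated correlation). Its call ended without mid-L3 control array 2 (adjusted p = 0.0611) and in the values as deposited (0.0557), in a range of 0.0150 to 0.0611. In the list for lipolysis and fatty acid oxidation, 3 of 14 rose and 1 fell (adjusted p = 0.55). The carnitine palmitoyltransferase gene whd, which feeds fatty acids into mitochondria, rose by 1.48 (SE 0.10, adjusted p = 1.8e-06), while its dimmer probe set gave -0.08, and bmm rose by 1.27 (SE 0.17, adjusted p = 3.5e-04).

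Genes of sugar handling moved both ways in mid-L3 larvae. In glycolysis, 3 of 12 rose and 1 fell (adjusted p = 0.34, and 0.0041 with the stage position as a covariate, range 0.0041 to 0.46), with Hex-C falling by 1.42 (SE 0.20, adjusted p = 4.3e-04) and its relative Hex-A rising by 0.51 (SE 0.10, adjusted p = 0.0056). In gluconeogenesis, trehalose and glycogen, 4 of 18 rose and 3 fell (adjusted p = 0.66). The trehalose transporter gene Tret1-1 rose by 1.17 (SE 0.07, adjusted p = 3.9e-07), the glycogen branching enzyme gene AGBE by 0.85 (adjusted p = 1.5e-04) and Tps1 by 0.75 (adjusted p = 9.7e-04). The sugar transporter gene sut1 fell by 1.18 (SE 0.09, adjusted p = 3.8e-06), Treh by 0.69 (adjusted p = 5.2e-04) and Sodh1 by 1.22 (adjusted p = 0.0020). Pepck1 gave -0.19 (adjusted p = 0.27) and fbp gave -0.13 (adjusted p = 0.58). Among 11 carbohydrases, 2 rose and 1, Amyrel, fell (adjusted p = 0.66 for the list), by 1.94 (SE 0.16, adjusted p = 4.8e-06), and tobi gave -0.69 (adjusted p = 0.17), passing with the mid-L3 arrays fitted alone (adjusted p = 0.0061, range 0.0061 to 0.52).

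Of 24 gut peptidases, 6 rose and none fell in mid-L3 larvae, or 8 and 0 adjusted over the list alone. The trypsin gene alphaTry rose by 1.93 (SE 0.08, adjusted p = 1.2e-08), from 1459 ± 148 to 6103 ± 197 (SD, n = 3), thetaTry by 2.54 (SE 0.38, adjusted p = 6.9e-04) and epsilonTry by 0.61 (SE 0.09, adjusted p = 5.2e-04). The list was called higher (adjusted p = 0.023, but adjusted p = 0.75 with an estimated correlation). That call was lost without mid-L3 control array 2 (adjusted p = 0.0797) or high sugar array 2 (0.0810), in a range of 0.0035 to 0.0810. Midgut markers held 3 higher and none lower of 11 (adjusted p = 0.24), with a median of -0.04 and a mean of 0.40. In the list for insulin, FOXO and TOR, 4 of 15 rose and none fell. AkhR rose by 1.09 (SE 0.14, adjusted p = 1.7e-04), ImpL2 by 0.65 (SE 0.13, adjusted p = 0.0051) and the kinase gene Pdk1 by 0.49 (SE 0.10, adjusted p = 0.0072), while InR gave 0.19 (adjusted p = 0.24) and NLaz gave 0.12 (adjusted p = 0.79). The insulin list was called higher (adjusted p = 0.023, but adjusted p = 0.37 with an estimated correlation), a call that ended without mid-L3 control array 2 (adjusted p = 0.0555, range 0.0118 to 0.0555).

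Of 17 genes of amino acid breakdown, 7 fell and 1 rose in mid-L3 larvae, or 9 and 3 adjusted over the list alone. The list was called lower (adjusted p = 0.0019, but adjusted p = 0.34 with an estimated correlation). Besides Hpd, the sarcosine dehydrogenase gene Sardh fell by 2.57 (SE 0.16, adjusted p = 6.9e-07). By contrast, Gs1, which encodes a glutamine synthetase that makes glutamine from glutamate, rose by 1.53 (SE 0.09, adjusted p = 3.0e-07), from 1535 ± 76.4 to 4848 ± 206 (SD, n = 3). Of 9 purine and urate genes, 3 fell (adjusted p = 0.023, but adjusted p = 0.52 with an estimated correlation), among them the xanthine dehydrogenase gene rosy (ry) by 1.95 (SE 0.17, adjusted p = 6.9e-06). Of 27 detoxification genes, 6 fell and 2 rose, without a call for the list (adjusted p = 0.067). It passed as lower without mid-L3 high sugar array 1 (adjusted p = 0.0368) or 3 (0.0433) and without both control arrays numbered 1 (0.0442). The list also passed in the values as deposited (adjusted p = 0.0488), without a filter on dim genes (0.0422) and with the replicate number as a block (0.0465), in a range of 0.0368 to 0.498. The glutathione transferase gene GstD4 fell by 1.85 (SE 0.23, adjusted p = 1.6e-04), the cytochrome P450 gene Cyp28d1 by 1.05 (SE 0.15, adjusted p = 5.2e-04) and catalase (Cat) by 0.63 (SE 0.08, adjusted p = 1.2e-04).

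Of 6 larval serum and lipid transfer proteins, 2 fell in mid-L3 larvae, or 5 adjusted over the list alone (adjusted p = 0.0081, but adjusted p = 0.24 with an estimated correlation). Mtp, which encodes the microsomal triglyceride transfer protein, fell by 0.67 (SE 0.10, adjusted p = 7.9e-04). The storage protein gene Lsp2 gave -0.13 (adjusted p = 0.14) and passed without mid-L3 high sugar array 2 (adjusted p = 0.0279, range 0.0148 to 0.43). Of 9 larval cuticle genes, 4 fell and none rose (adjusted p = 0.0056, but adjusted p = 0.24 with an estimated correlation), and Cpr78Cc fell by 1.79 (SE 0.15, adjusted p = 5.0e-06). The cuticle call ended with each array's stage position as a covariate (adjusted p = 0.0621, range 0.0024 to 0.0621). Ribosome biogenesis genes had a median of -0.32 and were called lower as a list (adjusted p = 0.0019, but adjusted p = 0.73 with an estimated correlation), with 1 of 21 higher, 1 lower, and none adjusted over the list alone by limma, although 11 had an unadjusted p under 0.05. That call ended without mid-L3 control array 2 (adjusted p = 0.0757, range 2.7e-05 to 0.0757). Testis markers were called higher (adjusted p = 0.0016, but adjusted p = 0.52 with an estimated correlation), with 3 of 12 higher, 9 adjusted over the list alone, and a median of 0.39. Sgs3 gave 0.82 with a wide spread (SE 0.93, adjusted p = 0.62).

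In limma's test, 1178 of the 8387 genes passed in mid-L3 larvae, 631 higher and 547 lower, of which 235 changed at least 2-fold, 106 higher and 129 lower. Of the 32 lists tested, 10 passed camera, 5 higher and 5 lower, and none with an estimated correlation, where 4 had an unadjusted p under 0.05. The fry test called 10 as moving in a direction and 24 as changing either way. The count of genes was 709 without mid-L3 control array 3, 735 without high sugar array 3, 1845 with the 6 mid-L3 arrays fitted alone and 2525 with array weights. With arrays centered on their medians, most of the genes that passed were lower, 775 against 494 higher.

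**Figure D2:**
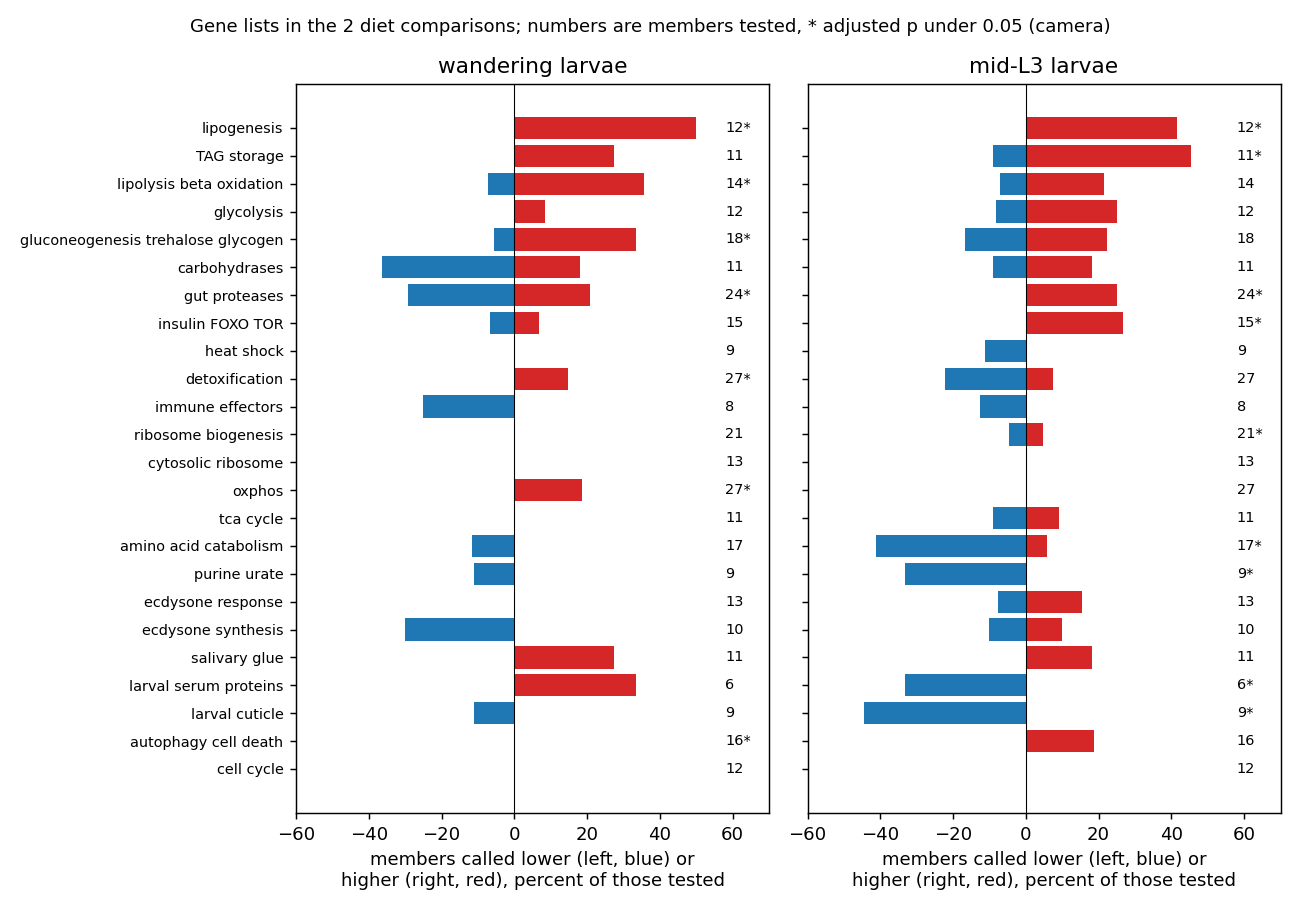
For the pathway lists, bars give the percent of tested members that were called lower (left) or higher (right) on high sugar food, in wandering larvae and in mid-L3 larvae, with the number tested and a star where the list passed camera. Lipogenesis had 6 of 12 genes higher in wandering larvae and 5 of 12 in mid-L3 larvae, and amino acid breakdown had 7 of 17 lower in mid-L3 larvae.

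A further comparison set the diet effects of the stages against each other. Stage and time on the diet change together in this design, so their parts in a difference cannot be told apart. Across the 8387 genes, the log2 changes at the stages correlated with Pearson's r of 0.303 and Spearman's rho of 0.206, where genes are not independent replicates. The comparisons share no arrays, but same-numbered control arrays of the stages deviated together. The products of their deviations gave 4.25% of the covariance of the log2 changes, and r without this part was 0.290. The values for independent lists that follow do not allow for it. In all, 94 genes rose at both stages, where independent lists would share 22.5, and 58 fell at both, where they would share 15.3. Opposite directions held 19 genes higher in wandering and lower in mid-L3 larvae, with 19.5 for independent lists, and 25 genes the other way, with 17.7. Both stages shared the increase of sug, Desat1, Lsd-1, Seipin, Tps1 and AkhR, and the decrease of Amyrel and Sodh1. Among genes with large changes at both stages, CG13946 rose by 3.22 (adjusted p = 0.0018) in wandering and 2.81 (adjusted p = 0.0023) in mid-L3 larvae, CG3348 rose by 4.46 and 2.40 (adjusted p = 4.7e-04) and vanin-like by 2.83 and 1.89 (adjusted p = 0.0088). CG8093 fell by 3.41 (adjusted p = 1.4e-05) and 3.56 (adjusted p = 5.3e-06), Jig by 3.97 and 2.64 (adjusted p = 2.7e-04) and CG18179 by 2.51 (adjusted p = 5.7e-05) and 2.49 (adjusted p = 3.5e-05).

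The test of the difference itself found 651 genes whose diet effect differed between the stages, 318 with the higher effect in wandering larvae and 333 with the lower. This balance moved with the scaling. With arrays centered on their medians, 57.6% of 660 genes had the higher effect in wandering larvae, and in the values as deposited 53.3% of 612. Cyp4e3 had a difference of 6.30 (SE 0.32, adjusted p = 3.8e-07), since its mid-L3 change was 0.12 (adjusted p = 0.79). The difference was 4.24 for Hpd (SE 0.24, adjusted p = 6.6e-07), 4.09 for the phosphatase gene Alp9 (SE 0.49, adjusted p = 2.5e-04), 3.88 for CG13230 and 3.76 for CG17362, all of which fell in mid-L3 larvae. It was -6.29 for CG6271 (SE 0.51, adjusted p = 1.1e-05), -5.58 for Lip3 (SE 0.44, adjusted p = 1.1e-05), -4.26 for PGRP-SB2 (SE 0.49, adjusted p = 1.9e-04), -3.52 for CG12951, -3.51 for PGRP-SC2 and -3.45 for Jon99Ci, all of which fell in wandering larvae. Among the genes followed in both comparisons whatever their change, Hex-C differed by 2.01 (adjusted p = 7.7e-04), Pepck1 by 1.51 (adjusted p = 6.8e-05), fbp by 0.90 (adjusted p = 0.0088) and ACC by -0.87 (adjusted p = 0.0090). The ACC call ended without both control arrays numbered 1 (adjusted p = 0.0557, range 2.7e-04 to 0.0557).

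Gut peptidases had a lower diet effect in wandering larvae for 9 of 24 genes and a higher one for 2 (adjusted p = 3.2e-06, but adjusted p = 0.35 with an estimated correlation), or 11 and 2 adjusted over the list alone. Midgut markers had 3 of 11 lower (adjusted p = 4.1e-04, but adjusted p = 0.32 with an estimated correlation). These were PGRP-SC2 and the peptidase genes Jon99Ci and alphaTry, which both lists share, so the marker list is no separate support. Carbohydrases had 2 of 11 lower (adjusted p = 0.0027, but adjusted p = 0.45 with an estimated correlation). Detoxification genes had a higher effect in wandering larvae for 7 of 27 (adjusted p = 3.2e-06, but adjusted p = 0.32 with an estimated correlation), or 13 higher and 1 lower adjusted over the list alone. Amino acid breakdown had 6 higher and 1 lower of 17 (adjusted p = 0.0052, but adjusted p = 0.32 with an estimated correlation). The list of larval serum and lipid transfer proteins had 3 higher of 6 (adjusted p = 8.9e-04, but adjusted p = 0.15 with an estimated correlation). These were Apoltp, Mtp and apolpp, and no storage protein gene was among them. Oxidative phosphorylation had 1 higher of 27 (adjusted p = 2.9e-04, but adjusted p = 0.47 with an estimated correlation), or 5 adjusted over the list alone. Insulin, FOXO and TOR had 2 lower of 15 (adjusted p = 0.011, but adjusted p = 0.32 with an estimated correlation). Autophagy had none of 16 in limma, 9 with an unadjusted p under 0.05 and 5 lower adjusted over the list alone (adjusted p = 7.0e-04, but adjusted p = 0.32 with an estimated correlation). These 9 of 32 lists passed camera, none with an estimated correlation, where 4 had an unadjusted p under 0.05, and fry called 9 as moving in a direction and 22 as changing either way. The count of 651 genes became 1277 without wandering high sugar array 2, 429 without mid-L3 control array 3, 428 without mid-L3 high sugar array 3 and 2206 with array weights.

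**Figure D3:**
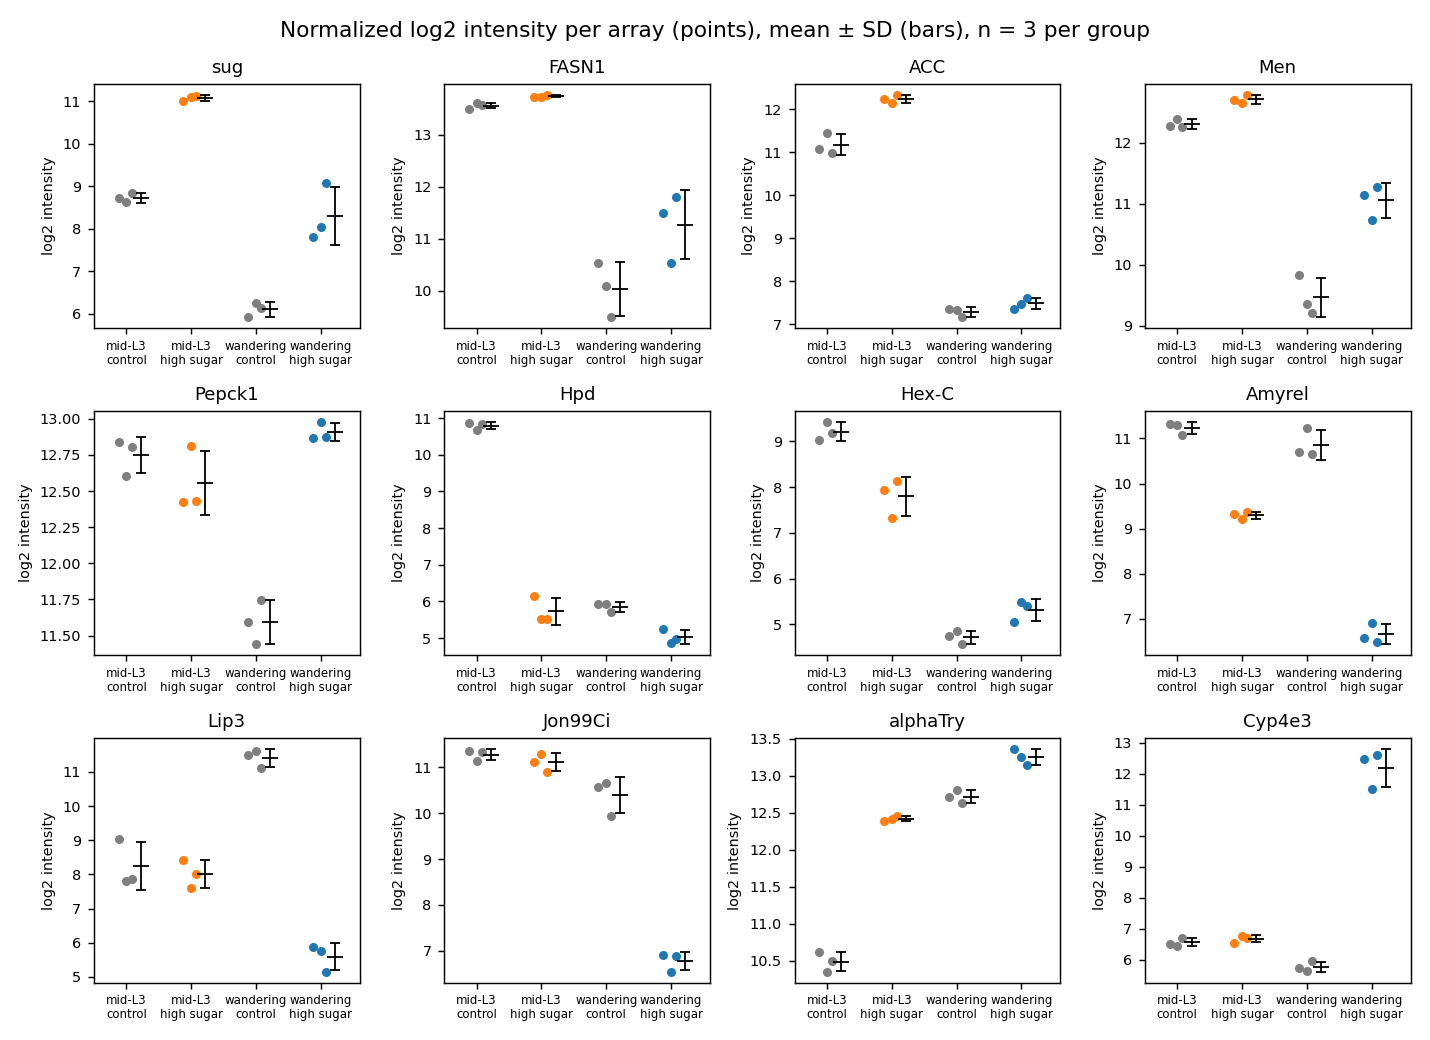
Normalized log2 intensity per array (points) with mean and SD (bars, n = 3) for 12 genes in the 4 groups of stage and diet. sug is higher on high sugar food at both stages, Cyp4e3, Lip3 and Jon99Ci separate the diets in wandering larvae, and Hpd separates them most in mid-L3 larvae.

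The stage comparison on control food is given as background to the diet effects. Besides developmental stage, the handling differs there, since only the mid-L3 larvae are described as spending their last 12 h on fresh food. On high sugar food the time on the diet also differs between the stages, so that comparison mixes development with exposure. On control food, glue proteins of the salivary gland were among the most raised in wandering larvae, with log2 changes of 8.65 for Sgs3 (SE 0.93, adjusted p = 1.9e-06), 8.39 for Sgs4, 7.68 for Sgs5 and 7.53 for Sgs1. The drosomycin-like gene Drsl5 rose by 7.13. Cuticle protein genes were among those that fell most, Cpr47Eg by 7.96, Lcp65Ag3 by 7.11, Lcp65Ae by 6.96 and Cpr67Fa1 by 6.88, with the glutathione transferase gene GstD7 falling by 6.83. All 27 genes of oxidative phosphorylation (adjusted p = 1.2e-09) and all 12 of glycolysis (adjusted p = 7.4e-05) were lower in wandering larvae, as were 23 of 27 detoxification genes (adjusted p = 5.7e-05), 9 of 11 of the citric acid cycle (adjusted p = 0.0021), 8 of 9 muscle markers (adjusted p = 0.0052) and 9 of 12 of lipogenesis (adjusted p = 0.0090). All 12 testis markers (adjusted p = 1.6e-05), 12 of 16 autophagy and cell death genes (adjusted p = 0.0052) and 7 of 8 salivary gland markers (adjusted p = 0.017) were higher. None of the lists passed with an estimated correlation, where their adjusted p lay between 0.38 and 0.45 and 3 lists had an unadjusted p under 0.05. Fry called 30 as moving in a direction and 32 as changing either way. In limma's test, 6642 genes (79.2%) passed on control food, 3305 higher and 3337 lower, and 6638 (79.1%) on high sugar food, 3207 higher and 3431 lower. The balance of directions moved with the scaling. In the values as deposited 3853 genes were higher and 2748 lower on control food, and 3824 and 2686 on high sugar food. With arrays centered on their medians 2993 were higher and 3668 lower on control food, and 2999 and 3617 on high sugar food. The changes of all genes correlated with the stage axis with Pearson's r of 0.032 for the wandering diet effect and 0.138 for the mid-L3 diet effect.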

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

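The splits of the arrays were chosen before the results were seen; the tests of mixed RNA, gut share, stage position and normalization in the paragraphs below were chosen only after the result was seen.

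The diet effect differed between the stages, by a test of the difference itself, for 651 genes and 9 gene lists. By camera with an estimated correlation 0 lists passed (lowest adjusted p = 0.15), 4 had an unadjusted p under 0.05, and fry called 9 in a direction and 22 either way. In 3 of 100 drawn exchanges of the diet labels within each stage, the real one included, as many genes passed as the 651, with 667 as the highest of the others. The other 2 keep the mid-L3 grouping and so the mid-L3 diet effect. Exchanging the labels of 1 whole stage, which was not among those drawn from the 200, gives 1256 genes, as it tests the sum of the diet effects. The exchanges remove or keep the diet effects themselves, so they do not test whether the effects are equal, and they leave open whether chance gives such a count of differences.

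Among genes that the report names, which were picked for large changes or as members of lists, the difference, wandering minus mid-L3 on the log2 scale, was 6.30 for Cyp4e3, 4.24 for Hpd, 4.09 for Alp9, 3.88 for CG13230, 3.76 for CG17362, 3.68 for CG34316, 2.34 for CG13947, 2.06 for CG3348 and 1.86 for ng2. It was -6.29 for CG6271, -5.58 for Lip3, -4.26 for PGRP-SB2, -3.52 for CG12951, -3.51 for PGRP-SC2, -3.18 for CG1774 and -2.66 for CG4716. Among genes of fat metabolism it was 1.18 for Men, 0.75 for yip2, -0.87 for ACC, -1.34 for whd and -2.18 for Agpat2, and the call for ACC ended without both control arrays numbered 1 (adjusted p = 0.0557, range 2.7e-04 to 0.0557). Among genes of sugar metabolism it was 2.01 for Hex-C, 1.51 for Pepck1, 1.33 for sut1, 0.90 for fbp, -0.55 for Hex-A, -0.62 for AGBE, -0.73 for Tret1-1, -1.50 for Mal-A7 and -2.26 for Amyrel. Among peptidases it was -3.45 for Jon99Ci, -2.39 for Jon44E, -0.80 for Jon66Ci, -1.40 for alphaTry and -0.45 for epsilonTry. Detoxification genes gave 2.18 for GstD4, 2.00 for Cyp4d1, 1.25 for GstE9 (a dimmer probe set gave -0.13) and 0.62 for Cat. The remaining genes gave 1.77 for Sardh, 1.77 for ry, -1.56 for Gs1, 0.48 for Cyt-c1, -0.67 for Pdk1, 0.60 for Mtp and 1.93 for Cpr78Cc.

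Antimicrobial transcripts, picked after their values were seen, were raised in the control array numbered 1 of both stages, where BomS2 lay at 2700 in mid-L3 control array 1 against 10.8 and 5.74 in the other controls, at 343, 514 and 107 in the mid-L3 high sugar arrays, and at 2742 against 36.6 and 25.3 in the wandering controls. Of 8 antimicrobial transcripts, 7 lay over 2-fold above the mean of the other controls in mid-L3 array 1, 4 in wandering array 1 and 3 in both, where 3.5 would be for independent sets. Over all genes, BomBc2, BomS2, BomS6 and CG8160 lay over 2-fold above each other control in array 1 of both stages, where 0.0837 would be for independent sets of 18 and 39 genes, and the other pairings of control arrays shared 0. Mixed RNA needs a share of 98.5% of wandering RNA in the mid-L3 array, while the glue transcripts allow -0.0977%, and 102% of mid-L3 RNA in the wandering array, while the cuticle transcripts allow 0.105%, which argues against both directions of mixing. Normalization is argued against by the excess in the values as deposited, with a median log2 of 2.89 in the stage where it was lower, and no biological explanation was tested, since no group of the design names an infection or a rearing batch.

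Gut peptidases changed in opposite directions on high sugar food in wandering larvae, with 5 genes higher and 7 lower, among them Jon99Fi at 1.73 (adjusted p = 8.7e-05) and Jon99Ci at -3.62. A smaller share of gut RNA stays open for the genes that were lower, since the opposite directions are the pattern itself and decide nothing about it. The arrays lay at 99.6 ± 4.95% of the stage axis on control food and at 100.4 ± 2.94% on high sugar food (SD, n = 3, exact permutation p = 0.8). A delay along this axis as the whole cause is argued against. A change toward mid-L3 no larger than the stage change, with a margin for error, allowed 3 of 12 genes. With the same limit an advance also allowed 3, but an advance past the wandering controls need not be bounded by it. The changes of 7 genes had the sign of their stage change and those of 5 the opposite sign, so an advance stays open for the 7. Jon99Ci fell by 3.62 against a stage change on control food of -0.88, Jon44E by 2.41 against -1.58, and Jon99Fi rose against a stage change of -0.97. The diet itself, which the design names, stays open, as does signal shared between related peptidases, since probe sequences were not analysed here.

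Of 17 transcripts of amino acid breakdown, 7 were lower on high sugar food in mid-L3 larvae and 1, Gs1, rose by 1.53, and the list was called lower (adjusted p = 0.0019, but adjusted p = 0.34 with an estimated correlation). The high sugar arrays lay further toward wandering, at 1.91 ± 2.41% of the stage axis against -1.91 ± 0.759% (SD, n = 3, exact permutation p = 0.1, the smallest these arrays can give). With the position as a covariate, 6 of 7 genes kept direction and call. The change of Gdh went from -0.52 to -0.38 (adjusted p = 0.0982). The covariate is linear and was fitted on the spread of arrays within groups, so it cannot remove an early drop particular to a gene. All 7 genes but Oat (0.53) also fell from mid-L3 to wandering larvae on control food, among them Hpd (-4.94), Faa (-3.78) and Sardh (-1.27). The covariate therefore does not decide on a more advanced stage as the whole cause. Normalization is argued against by 6 of 7 genes that kept direction and call in the values as deposited, where Tdh lay under the filter. A more advanced stage and the diet itself stay open.

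The remaining splits are too few for a share under 0.05, since 6 arrays make 10 splits. The real split gave 534 genes for the wandering diet with 127 as the highest other, and 1178 for the mid-L3 diet with 1 as the highest other. For the stages it gave 6642 on control food and 6638 on high sugar food, each with 0 as the highest other by limma, also among the 3 other splits on control food that part all 3 same-numbered pairs. In each of these comparisons 1 split, the real one, gave as many genes. A split that mixes the groups adds any real difference between them to the spread the test divides by, which lowers its count. The low counts of the other splits are therefore no further evidence, and only the rank of the real split counts.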

How the results depend on the processing

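The alternatives without both control arrays numbered 1, with the stage position as a covariate and with a block in the control arrays are tests chosen only after the data were seen. Of 127 results of named genes, 110 passed, and none of these 110 changed direction under the alternatives run. Among those that did not pass, ImpL2 and Lsp2 in wandering larvae and NLaz and Sgs3 at both stages took both signs. Of the 110, 104 passed under each alternative run for them and 6 did not under at least 1 (ACC in the interaction, and Cyt-c1, FASN1, Hpd, Sardh and fbp in wandering larvae). The 2-fold condition was not applied to named genes, and the filter at the 50th percentile kept 113 of the 127 results. Many of these genes were picked for large changes or small adjusted p, so the counts do not describe all genes that passed. With the 6 wandering arrays alone, 199 of the 503 wandering diet genes still tested kept their call. The correlation of the diet effects was 0.274 to 0.328 with each array left out (jackknife SE 0.0521).

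The wandering diet count of 534 genes was 213 with its 6 arrays alone, 2381 with array weights, 144 with a 2-fold change required, 328 without both control arrays numbered 1, and 275 to 1421 with each array left out. It was lowest without wandering control array 3 (275), was 317 and 295 without high sugar arrays 1 and 3, and was highest without high sugar array 2 (1421), which keeps 519 of 531 genes. The mid-L3 diet count of 1178 was 1845 with its 6 arrays alone, 2525 with array weights, 235 with a 2-fold change required and 709 to 998 with each array left out (709 without control array 3, 735 without high sugar array 3). The interaction's 651 was 2206 with array weights, 255 with a 2-fold change required and 428 to 1277 with each array left out (1277 without wandering high sugar array 2, 429 without mid-L3 control array 3, 428 without mid-L3 high sugar array 3). The stage counts were 3333 on control food and 3154 on high sugar food with a 2-fold change required. That condition lowers counts by construction, and for the other alternatives the cause was not tested. The array weights ran from 0.237 for wandering high sugar array 2 to 4.02 for wandering high sugar array 1, and their fit stopped before reaching its tolerance.

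With an estimated correlation, 0 lists passed camera in the wandering diet, mid-L3 diet, interaction and control food stage comparisons (1, 4, 4 and 3 at an unadjusted p under 0.05), and fry called 21, 24, 22 and 32 as changing either way and 9, 10, 9 and 30 in a direction. The cause was not tested.

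With the replicate number as a block, the counts were 430, 1046, 556, 6561 and 6541 genes and 8, 11, 9 and 13 lists, and 409 of 534 wandering genes passed again. The block changed the call of the detoxification list in mid-L3 larvae (adjusted p = 0.0465, range 0.0368 to 0.498) and of carbohydrases between the stages on control food (0.0365, range 0.0127 to 0.0717). Carbohydrases also passed there without wandering control array 1 (0.0268), 2 (0.0439) or 3 (0.0488) and without mid-L3 control array 2 (0.0466) or 3 (0.04997). By the rule that every same-numbered pair lie over 0.1, only the control arrays of the stages deviated together by number. With these 6 arrays alone and the number as a block, 6688 genes and 14 lists passed, carbohydrases (0.0444) and salivary glue (0.0394, range 0.0293 to 0.197) among them, with 6457 of 6559 genes kept. These arrays also enter the interaction, where a block in the control arrays alone gave 566 genes and 9 lists, with 544 of 651 genes kept, and changed no call of the 15 genes followed there or of a list. No other pair of groups met that rule, although same-numbered arrays of the wandering diets correlated at -0.252 to 0.262, the highest being the arrays numbered 1. Over all groups, the control arrays included, 3 of 12 arrays correlated best with their own number, and the median residual correlation of all same-number pairs was -0.0170. In the values as deposited the counts were 453, 1213, 612, 6601 and 6510, and the median of all genes in the stage comparison on control food was 0.18, against -0.12 with centered medians. With the stage covariate they were 621, 864 and 601. Dim genes limit the results, since the added constant shrinks their changes.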

Other observations

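The families in this part were grouped by symbol and tests of them were chosen only after the data were seen. Among 57 cytochrome P450 genes (Cyp), 18 were lower and 2 higher on high sugar food in mid-L3 larvae (adjusted p = 2.9e-04, but adjusted p = 0.44 with an estimated correlation), and 17 and 2 in the values as deposited. Cyp4s3 gave -2.29 (adjusted p = 1.5e-04), Cyp28d2 gave -1.21 (adjusted p = 5.2e-06) and Cyp6v1 gave -1.14 (adjusted p = 6.1e-05). In wandering larvae 7 were higher and 6 lower (adjusted p = 0.57), with Cyp9b1 at 1.77 (adjusted p = 3.4e-04), and the difference between stages had 11 higher and 2 lower (adjusted p = 1.2e-05, but adjusted p = 0.40 with an estimated correlation). Among 13 Jonah peptidases, 7 were lower and 1 higher in wandering larvae (adjusted p = 1.9e-08, but adjusted p = 0.13 with an estimated correlation). Among 69 genes of mitochondrial ribosomal proteins, 5 were lower and none higher in mid-L3 larvae, a share near that of all genes (547 of 8387 lower). Their median was -0.20 (camera adjusted p = 1.0e-06, but adjusted p = 0.73 with an estimated correlation).

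The chitinase gene Cht4 gave -1.76 in wandering and -1.80 in mid-L3 larvae (adjusted p = 0.0024 and 9.5e-04), and the phosphatase gene Alp4 gave 1.38 and 2.21 (adjusted p = 2.3e-05 and 3.0e-07). The odorant-binding protein gene Obp56d rose by 1.59 in mid-L3 larvae (adjusted p = 7.0e-09), against 0.11 in wandering larvae (adjusted p = 0.31), and its difference passed the test (adjusted p = 6.6e-07).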
